A study of Drosophila melanogaster with 12 samples.

How the data were processed

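The series holds 12 Affymetrix DrosGenome1 arrays of RNA from whole Drosophila melanogaster, 1 array per hour for hours 1 to 12 after adults kept without yeast since the third larval instar were returned to food with yeast. The labels give 1 treatment for these arrays and no sex, so hour was the only factor. Arrays of flies left without yeast and arrays made before the time course were not analysed here. Hour therefore cannot be separated from time of day, age, handling order or array processing. Nothing says how many flies or cultures stand behind each array, and p-values measure only the spread between these arrays around a curve over hours, which may be technical.

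Per the labels, the authors extracted RNA with Trizol and normalized the arrays with dChip using an invariant probe selection; the version, background model and probe masking are not given in the sources used here. The deposited values are intensities on a linear scale, between which no further normalization was applied. The table has 14010 probe sets, of which 44 are control probe sets and 13966 measure fly transcripts. All columns of the table belonged to the 12 arrays. Arrays give no read depth, and their number limits the precision.

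Values under the 20th percentile of the whole table, an intensity of 57.2, were set to that floor before taking log2. Fly probe sets above the floor on at least 3 arrays were tested, which kept 11586 and left out 2380. The platform annotation gives 12443 probe sets 1 gene symbol, 327 several genes, and 1196 are unnamed here. No symbol needed updating through the gene table of assembly Release 6 plus ISO1 MT, in which 49 probe sets had an Entrez identifier that was not found. That table served for names only, and no coordinates are given. Genes with several probe sets (1209 of 10844) were represented in gene lists by the probe set with the highest mean, giving 9224 tested genes.

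Tests used R 4.3.3 and limma 3.58.1 with Benjamini-Hochberg adjustment and a threshold of 0.05. The main result was the slope on hour, given as the fitted log2 change over the 11 hours from hour 1 to hour 12, with its standard error. Further fits were a quadratic term, 3 windows of 4 hours, and a search for a single step with at least 2 arrays on each side, whose p came from 100 random orders of the arrays pooled over probe sets. The labels mention change-point analysis without describing it. The 34 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated for each list, and with fry. Counts of list members come from the gene-level fit and printed adjusted p of single genes from the probe-set fit. Correlations of array measures with hour used 100000 permutations, two-sided.

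Genes were named by a rule fixed before the data were examined, as were the lists and tests. Among probe sets with 1 symbol, past the threshold and above the floor on all 12 arrays, it takes the 10 largest rises and 10 largest falls of the trend and the 5 largest of each kind in the quadratic term and window contrasts. Whether or not these conditions hold, it also takes the 3 members of each list with the smallest p, and InR, foxo, Ilp2, Lip4, per, tim, Yp1, Yp2 and Yp3. Thor, srl, Ilp3, Ilp5 and Ilp6 were also on it and were not analysed here. The text leaves out some of these genes, and any other gene is said to be chosen after its values were seen. Direction words are used only for genes past the threshold.

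The procedure was tested on simulated data in which 200 of the 11586 probe sets changed. For the linear trend it recovered 59.7% of changes of 0.5 log2, 91.0% of 1 and 100% of 2, with 11 unchanged probe sets called. The step search recovered 58.2%, 94.0% and 100%, with 8 unchanged called. The simulated spread was independent between probe sets, unlike the real arrays. Other settings chosen at that time were quantile and median normalization, other floors and filters, another variance model, each hour left out, odd or even hours, ranks, log2 of hour, larger step segments, and the mean over a gene's probe sets. Added after seeing the data were the mean of male accessory gland transcripts as covariate, the fit without the 5 arrays holding them, and the 3' to 5' differences of control transcripts as covariates, each of 3 transcripts alone, all 3 averaged, and actin with eIF4A. The detoxification list without its cyclophilins was added then too.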

Results

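The data follow the transcripts of whole flies through the first 12 hours of renewed yeast feeding, after the flies had lived without yeast from late larval life until some days after emergence. Each hour has 1 array and no array was repeated. Median intensities lay between 113.7 at hour 2 and 120.3 at hour 9, and between 18.7% and 20.9% of fly probe sets were at or under the floor. The first principal component held 35.5% of the variance and the second 22.3%.

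The yolk protein genes and the protease gene Jon25Bii had the largest rises over the 12 hours among probe sets above the floor on all 12 arrays, and 25 of 61 genes of nerve, eye and muscle fell. Yp1, Yp2 and Yp3, which encode the yolk proteins taken up by the egg, rose by a fitted log2 change of 2.96 ± 0.24, 2.95 ± 0.25 and 2.56 ± 0.25 (SE, n = 12 arrays). Their limma adjusted p were 3.11e-05, 3.11e-05 and 8.31e-05. Jon25Bii, a serine protease of the Jonah family, rose by 3.01 ± 0.36 from an intensity of 232.3 at hour 1 to 2587 at hour 12 (limma adjusted p = 0.000247). Of 66 genes of mitochondrial ribosomes 48 rose, as did 22 of 37 of the proteasome and 19 of 29 of the secretory pathway, while cytosolic ribosomal proteins had a median fitted change of 0.00. The mitochondrial ribosomal, proteasome and secretory lists passed at a preset correlation between genes, and none of them did with an estimated one. The question addressed is which transcripts follow the hours after yeast returns.

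In all, 1554 of 11586 probe sets (13.4%) had a limma trend past the threshold, 978 higher and 576 lower in later hours. Of these 68 at least doubled and 32 at least halved. The other genes among the 10 largest rises, counted over probe sets of a named gene above the floor on all 12 arrays, had varied roles. The precursor gene of the main lipid-carrying protein of the blood, apolpp, rose by 1.96 ± 0.25, the desaturase Fad2 by 1.62 ± 0.30, smp-30 by 1.42 ± 0.20 and the amylase Amy-d by 1.42 ± 0.22. A second probe set for apolpp rose by 1.06. CG6295 rose by 1.47 ± 0.23 and CG15818 by 1.43 ± 0.28, the latter by less, 0.87, and without a call when the 5 arrays that held male transcripts were left out (limma adjusted p = 0.0536). The largest fall was that of CG4716, by -2.43 ± 0.42, from an intensity of 613.3 at hour 1 to 101.1 at hour 12. BomS6, an immune-induced peptide gene, changed by -1.82 ± 0.22, the photoreceptor dehydrogenase Pdh by -1.49 ± 0.18 and tan (t), an enzyme of transmitter recycling in the eye, by -1.38 ± 0.11. The kinase gene Lk6 fell on both of its probe sets, by -1.37 ± 0.36 and -1.36 ± 0.15, although the first lost its call without hour 1, at a smaller change of -0.90 (limma adjusted p = 0.118), or hour 12, at -1.46 (0.0525). Also lower were lncRNA:CR42862 (-1.36 ± 0.27, and -1.13 on another probe set), lncRNA:CR31781 (-1.29 ± 0.11, and -0.65 on another), Culd (-1.25 ± 0.19) and osi (-1.20 ± 0.23). A measure of RNA quality moved with the hours too, the log2 difference between the 3' and 5' control probe sets of actin. Its 5' probe set was dim, at 99.2 at hour 1 and 161.1 at hour 12. Control probe sets without a fly target read up to 102.6 at hour 1 and 135.2 at hour 12, leaving aside yeast ones and the bright spike-in controls (BioB, BioC, BioDn and CreX). The difference may therefore follow the level of actin and not RNA quality, which was not tested. The actin difference went from 1.13 at hour 1 to 0.69 at hour 12. Against hour it had Pearson r = -0.80 (permutation p = 0.00281, adjusted over 6 array measures 0.0169; Spearman rho = -0.78, permutation p = 0.00392, adjusted 0.0235; r = -0.68 without hours 1 and 12). For eIF4A r was -0.55 (permutation p = 0.0633, adjusted 0.19; rho = -0.51, permutation p = 0.0945, adjusted 0.284; r = -0.50 without hours 1 and 12), and for GAPDH it was 0.10 (permutation p = 0.794, adjusted 0.794; rho = -0.22, permutation p = 0.499, adjusted 0.587; r = 0.14 without hours 1 and 12). The mean log2 intensity of the spike-in controls was highest at hour 1, at 10.75, and lowest at hour 12, at 9.41. Against hour its Pearson r was -0.45 (permutation p = 0.144, adjusted 0.288; r = 0.15 without hours 1 and 12). With the actin difference as covariate, added after seeing the data, 228 probe sets were called, 208 of them among the 1554. The fitted changes of the 1554 were about as large with it, at a median ratio of 1.04 and with the same sign, and their median SE went from 0.12 to 0.20, since actin follows hour. Calls numbered 997 without hour 1, 1030 without hour 2, 943 without hour 11 and 996 without hour 12, and 848 without the 5 arrays that held male transcripts.

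**Figure D1:**
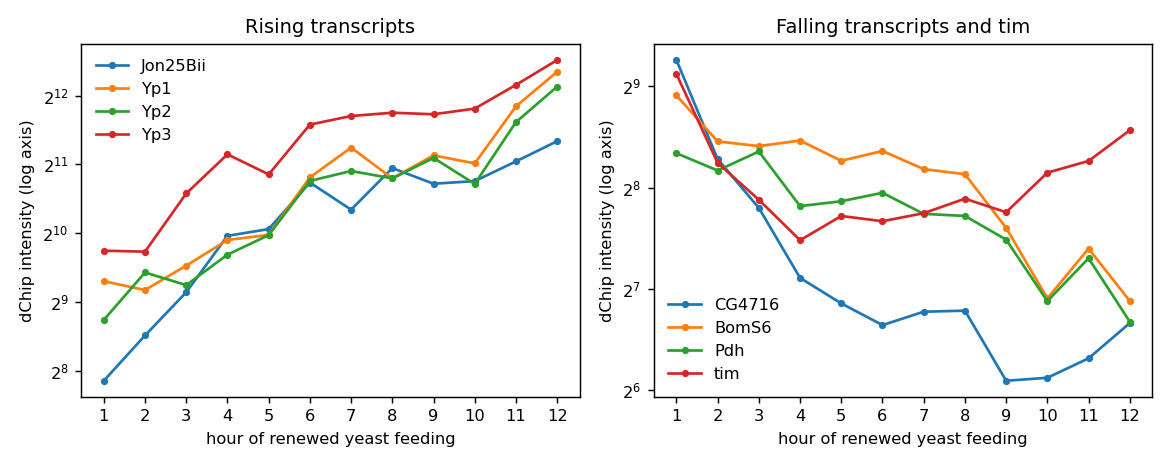
Intensity per array (log axis) against hour of renewed yeast feeding, 1 point per array and no error bars because each hour has 1 array. Yp1 went from 632.3 at hour 1 to 5204 at hour 12 and Jon25Bii from 232.3 to 2587, while CG4716 went from 613.3 to 101.1 and tim from 557.3 through 178.4 at hour 4 to 378.9.

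Most genes of mitochondrial ribosomal proteins rose. Of 66 mitochondrial ribosomal protein genes 48 rose, 0 fell and 18 did not pass (55 rose adjusted over the list alone), among them mRpL12 by 0.88 ± 0.10, mRpL36 by 0.60 ± 0.07 and bonsai by 0.88 ± 0.12. A second probe set for mRpL12 did not pass, at -0.15. The limma camera adjusted p was 3.58e-22, and adjusted p = 0.192 with an estimated correlation. Of 37 proteasome genes 22 rose, 1 fell and 14 did not pass (24 rose adjusted over the list alone), with Prosalpha6 at 0.83 ± 0.09, Rpn3 at 0.85 ± 0.10 and Prosbeta3 at 0.57 ± 0.07. The limma camera adjusted p of the proteasome list was 1.72e-10, and adjusted p = 0.192 with an estimated correlation. Of 29 genes of the secretory pathway and protein folding in the endoplasmic reticulum 19 rose, 1 fell and 9 did not pass (22 rose adjusted over the list alone). Sec61alpha, a subunit of the translocation channel, rose by 1.24 ± 0.13, twr by 1.04 ± 0.15 and Pdi by 0.58 ± 0.10 (limma camera adjusted p = 2.59e-10; adjusted p = 0.25 with an estimated correlation). Of 18 tRNA synthetase genes 10 rose and 8 did not pass (17 rose adjusted over the list alone), including SerRS at 0.59 ± 0.13 and ArgRS at 0.71 ± 0.17 (limma camera adjusted p = 2.15e-07; adjusted p = 0.271 with an estimated correlation). The actin 3' to 5' difference fell alongside these groups. The count of secretory genes that rose was 12 without hour 1, and 0 fell without hour 2, 3, 11 or 12. That of tRNA synthetases was 4 without hour 1, 3 without hour 2, 16 without hour 10, 4 without hour 11 and 5 without hour 12. Without hour 1 the limma adjusted p of SerRS was 0.0502, and its second probe set had a change of 0.03.

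Some genes of growth and replication rose. Of 43 genes of DNA replication and the cell cycle 15 rose and 28 did not pass (18 rose adjusted over the list alone), such as RPA2 by 0.48 ± 0.07, RfC4 by 0.44 ± 0.08 and dUTPase by 0.96 ± 0.18 (limma camera adjusted p = 7.66e-08; adjusted p = 0.192 with an estimated correlation). The count was 9 without hour 2 and 7 without hour 12. Of 41 ribosome biogenesis genes 6 rose, 1 fell and 34 did not pass (13 rose adjusted over the list alone), with NHP2 at 0.96 ± 0.23 and mod at 1.04 ± 0.26 (limma camera adjusted p = 9.5e-05; adjusted p = 0.506 with an estimated correlation). Without hour 1, 0 of these genes rose or fell, and the count that rose was 2 without hour 2, 3 without hour 11 and 14 without hour 10. The count that fell was also 0 without hour 2, 3, 6, 7, 8, 9, 10 or 12, and 9 rose without hour 6. Without hour 1 the limma adjusted p of NHP2 was 0.0772 and that of mod 0.088, and mod also lost its call without hour 2 (0.0559) or hour 11 (0.0525). Of 37 translation factors 9 rose, 1 fell and 27 did not pass (17 rose and 4 fell adjusted over the list alone). The helicase gene eIF4A fell by -0.50 ± 0.06, while eIF2beta rose by 0.72 ± 0.15 (limma camera adjusted p = 0.0096; adjusted p = 0.58 with an estimated correlation). Of 16 chaperone genes 7 rose, 1 fell and 8 did not pass (8 rose adjusted over the list alone), the cytosolic chaperonin subunits CCT1 by 0.74 ± 0.12 and CCT5 by 1.06 ± 0.18 (limma camera adjusted p = 0.0204; adjusted p = 0.448 with an estimated correlation). The exception was the small heat shock gene l(2)efl, which changed by -0.81 ± 0.14. The camera calls for ribosome biogenesis, translation factors and chaperones did not pass with the actin and eIF4A 3' to 5' difference as covariate (limma camera adjusted p = 0.0668, 0.0996 and 0.177). Their median changes went from 0.28, 0.28 and 0.38 to 0.22, 0.26 and 0.46. With all 3 control transcripts averaged, the medians were 0.19 for ribosome biogenesis and 0.16 for translation factors. Neither list passed with that covariate (limma camera adjusted p = 0.0751 and 0.213), while the chaperone list kept its call. Since these covariates follow hour, how much of the changes is kept cannot be told. Translation factors had 5 that rose and 3 that fell without hour 2, 2 that fell without hour 8 and 17 that rose without hour 10. Chaperones had 2 that fell without hour 10. Their list call was lost without hour 2 (limma camera adjusted p = 0.0611), and that for chaperones without hour 1 (0.0701).

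Reproductive and fat body genes were mixed. In the list of egg shell and yolk genes, of 19 members 3 rose and 16 did not pass (3 rose adjusted over the list alone), and the 3 were Yp1, Yp2 and Yp3, so that the list's median change was 0.13 and its mean 0.61 (limma camera adjusted p = 0.00254; adjusted p = 0.241 with an estimated correlation). Of 26 germ line and early oogenesis genes 9 rose, 2 fell and 15 did not pass (10 rose and 3 fell adjusted over the list alone), with alphaTub67C at 0.90 ± 0.12, exu at 1.26 ± 0.22 and vas, above the floor on 11 arrays, at 1.05 ± 0.19 (limma camera adjusted p = 0.00704; adjusted p = 0.506 with an estimated correlation). With the floor at the 40th percentile vas changed by 0.45 and lost its call (limma adjusted p = 0.0965). Of 11 storage and circulating fat body proteins 4 rose and 7 did not pass (5 rose adjusted over the list alone), including smp-30 and Apoltp, the latter by 0.76 ± 0.16 (limma camera adjusted p = 0.0372; adjusted p = 0.288 with an estimated correlation). Of 12 fatty acid oxidation genes 6 rose and 6 did not pass (10 rose adjusted over the list alone), among them Echs1 at 0.45 ± 0.08 and Acsl at 0.51 ± 0.10 (limma camera adjusted p = 4.51e-05; adjusted p = 0.25 with an estimated correlation). Of 29 genes of amino acid transport and catabolism 6 rose and 23 did not pass (8 rose adjusted over the list alone), such as the aminotransferase Got2 by 0.98 ± 0.12 and Shmt by 1.19 ± 0.24 (limma camera adjusted p = 0.00611; adjusted p = 0.271 with an estimated correlation). Germ line genes that rose numbered 5 without hour 1, 4 without hour 2, 3 without hour 11 and 3 without hour 12, fatty acid oxidation genes 3 without hour 3, 4, 11 or 12, and fat body genes 2 without hour 12. The germ line call was lost without hour 12 (limma camera adjusted p = 0.102) and the fat body call without hour 3 (0.0812) or hour 10 (0.0516). With the strict filter the germ line call was lost too (limma camera adjusted p = 0.0589). Both were lost with log2 of hour (limma camera adjusted p = 0.0814 and 0.106) and in odd hours (0.312 and 0.0875). With the actin 3' to 5' difference as covariate the fat body and amino acid lists did not pass (limma camera adjusted p = 0.0936 and 0.175), with medians of 0.08 and 0.12 after 0.16 and 0.15.

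Part of the transcripts of nerve, eye and muscle fell. Of 21 nervous system genes 9 fell, 0 rose and 12 did not pass (13 fell adjusted over the list alone). The GABA receptor gene Rdl changed by -0.93 ± 0.12, elav by -0.90 ± 0.13 and nSyb by -0.84 ± 0.15 (limma camera adjusted p = 5.82e-10; adjusted p = 0.0712 with an estimated correlation). Of 17 eye and photoreceptor genes 8 fell and 9 did not pass (8 fell and 1 rose adjusted over the list alone), with the arrestin Arr2 at -0.89 ± 0.10, Gbeta76C at -1.07 ± 0.12 and inaD at -0.73 ± 0.10 (limma camera adjusted p = 6.37e-06; adjusted p = 0.192 with an estimated correlation). Of 23 muscle genes 8 fell and 15 did not pass (8 fell and 2 rose adjusted over the list alone), with Zasp66 at -1.10 ± 0.11, tn at -0.96 ± 0.13 and Mlc2 at -0.41 ± 0.07 (limma camera adjusted p = 2.4e-05; adjusted p = 0.192 with an estimated correlation). The actin 3' to 5' difference fell in the same hours. In muscle 1 gene rose without hour 1 or hour 10.

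Among nutrient signalling genes 3 of 24 in the insulin and TOR list and 5 of 22 in the FOXO and fasting list passed. Of the 24 insulin and TOR signalling genes 3 fell and 21 did not pass (3 fell adjusted over the list alone). The first, ImpL2, which encodes a secreted insulin-binding protein, changed by -0.58 ± 0.13, chico, the insulin receptor substrate, by -0.30 ± 0.08 and REPTOR by -0.74 ± 0.23 (limma camera adjusted p = 0.0383; adjusted p = 0.444 with an estimated correlation). Without the 5 arrays that held male transcripts ImpL2 changed by -0.37 and lost its call (limma adjusted p = 0.187), and REPTOR changed by -1.12 and kept it. Without them the list did not pass (limma camera adjusted p = 0.0789), nor did the FOXO and fasting list (limma camera adjusted p = 0.0892). Only 1 gene fell without hour 1, 11 or 12. The list lost its call without hour 1 (limma camera adjusted p = 0.338), hour 9 (0.09) or hour 10 (0.0502), and with the floor at the 40th percentile (0.0509). Its mean log2 intensity, minus the mean over the arrays, was 0.27 at hour 1 and between -0.06 and 0.02 at each later hour. The median change was -0.03, but 0.04 without hour 1, so the downward call rests largely on that array. The call of chico was lost without hour 1 (limma adjusted p = 0.101), hour 11 (0.0591) or hour 12 (0.0815). REPTOR lost its call without hour 1, where its change was -0.45 (limma adjusted p = 0.212). It also lost it, at changes from -0.70 to -0.78, without hour 2 (0.0838), 4 (0.0726), 7 (0.0564), 8 (0.0608), 9 (0.0672), 11 (0.0801) or 12 (0.121). The fitted changes of InR (-0.46 ± 0.19, limma adjusted p = 0.136), foxo (-0.05 ± 0.12, limma adjusted p = 0.877) and Ilp2 (0.02 ± 0.13, limma adjusted p = 0.97) did not pass. InR read 252.6 at hour 1, 146.5 at hour 2 and 122.2 at hour 9. Of 22 FOXO-linked and fasting-linked genes 1 rose, 4 fell and 17 did not pass (1 rose and 5 fell adjusted over the list alone), with Atg8a at -0.95 ± 0.17 and Atg1 at -0.71 ± 0.22 (limma camera adjusted p = 0.0393; adjusted p = 0.483 with an estimated correlation). No gene of this list rose without hour 1, 2, 3, 5, 9, 11 or 12 (0 in each). It lost its call without hour 1 (limma camera adjusted p = 0.386), 2 (0.0556), 9 (0.0807) or 10 (0.0616). The call was also lost with median normalization (0.0506), the floor at the 40th percentile (0.0509), no filter (0.0531), the strict filter (0.0527) or the eIF4A covariate (0.0737). The list's median change was -0.03, but 0.07 without hour 1. Atg1 lost its call without hour 1, where its change was -0.44 (limma adjusted p = 0.224). It also lost it, at changes from -0.68 to -0.76, without hour 2 (0.0976), 3 (0.0529), 6 (0.058), 9 (0.0631), 11 (0.0859) or 12 (0.139).

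**Figure D2:**
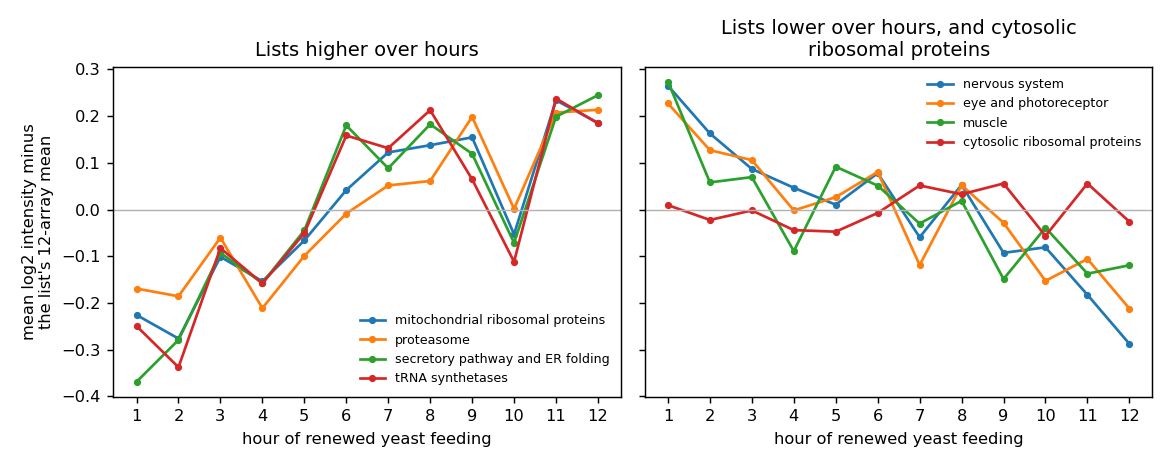
Mean log2 intensity of each list's tested genes, minus the list's mean over the 12 arrays, against hour; 1 point per array, no error bars. The nervous system, eye and muscle lists go down over the hours, and cytosolic ribosomal proteins have a median fitted change of 0.00. The 4 lists on the left go up, but not evenly, and each drops at hour 10. Mitochondrial ribosomal proteins are at 0.15, -0.05 and 0.23 at hours 9, 10 and 11.

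Male transcripts were present on some arrays. Acp95EF, made in the male accessory gland, had intensities of 269.5, 331.3, 552.0, 477.4 and 478.3 at hours 2, 3, 5, 9 and 10, and between 38 at hour 6 and 44 at hour 4 on the other 7 arrays. The testis transcript Mst84Dd read 517.9, 564.2, 437.9, 351.8 and 277.4 at those hours and between 109.2 and 127.2 on the other arrays. Of 22 testis genes 2 fell and 20 did not pass (2 fell adjusted over the list alone), bol by -0.60 ± 0.11 and Prosalpha4T1 by -0.52 ± 0.11 (limma camera adjusted p = 0.00764; adjusted p = 0.537 with an estimated correlation). Without the 5 arrays neither gene passed (limma adjusted p = 0.0691 and 0.0745), nor did the list (limma camera adjusted p = 0.911), and the list also lost its call without hour 2 (0.0863). With the floor at the 40th percentile Prosalpha4T1 changed by -0.28 and lost its call (limma adjusted p = 0.0862). Without the 5 arrays the list of fat body proteins did not pass (limma camera adjusted p = 0.164). Of 106 named probe sets past the threshold, 32 lost their call without the 5 arrays, and not all are listed in the text. Among them, at changes of similar size, were CG4716 (limma adjusted p = 0.0709), lncRNA:CR42862 (0.105), Pdi (0.0637), SerRS (0.058), ArgRS (0.111) and eIF2beta (0.061). The same held for mod (limma adjusted p = 0.0668), Echs1 (0.0822), Atg8a (0.0945), Atg1 (0.137), Clk (0.088), CtsL1 (0.0853) and CG34357 (0.159). Of 10 male accessory gland genes 0 passed (limma camera adjusted p = 0.402, and 0.0453 without hour 1).

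**Figure D3:**
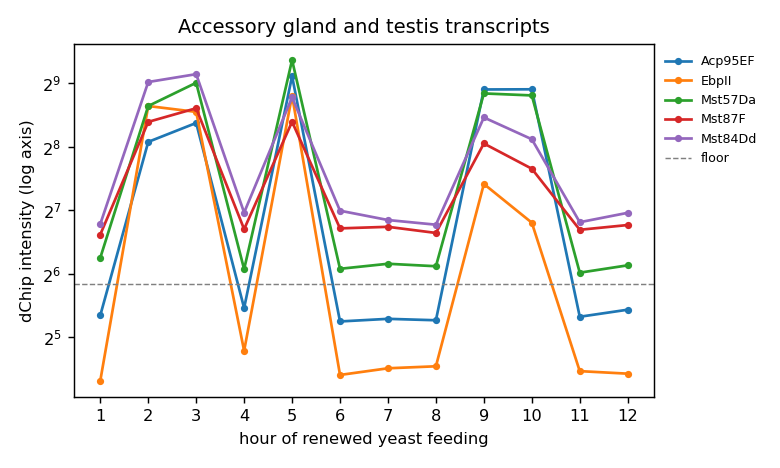
Intensity per array (log axis) against hour for transcripts of the male accessory gland (Acp95EF, EbpII, Mst57Da) and testis (Mst87F, Mst84Dd); the dashed line is the floor of 57.2 and each point is 1 array. All 5 are highest at hours 2, 3, 5, 9 and 10.

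The other 15 lists did not pass in the camera test, though single members did. Of 24 digestive protease genes 6 rose, 6 fell and 12 did not pass (6 rose and 8 fell adjusted over the list alone). Their median change was -0.07, the mean 0.18 and the direction of the test downward (limma camera adjusted p = 0.449). Jon25Biii rose by 1.31 ± 0.17. Jon25Bi read 22.8, 29.9 and 40.4 at hours 1 to 3, under the floor of 57.2, and 280.2 at hour 12; its fitted change with the early values at the floor was 2.25, which does not measure its rise. Without hour 11 or 12, 3 protease genes fell. Among 24 carbohydrate-digesting enzymes and lysozymes 5 rose and 2 fell (limma camera adjusted p = 0.248), among them Mal-A6, which rose by 1.55 ± 0.26 and was above the floor on 11 arrays. With the floor at the 40th percentile Mal-A6 rose by 0.95 (limma adjusted p = 0.0301), while Clk of the clock list changed by -0.12 and lost its call (limma adjusted p = 0.375). Of these enzymes 1 fell without hour 1 or hour 2. Of 30 lipid synthesis and storage genes 9 rose and 3 fell (limma camera adjusted p = 0.124, but 0.00877 without hour 1 and 0.0442 without hour 10). The counts were 5 and 1 without hour 2 or 11, and 1 fell without hour 4 or 12. Of 22 clock genes and clock outputs 1 rose and 5 fell (limma camera adjusted p = 0.0513, but under 0.05 without any 1 of hours 2, 3, 4, 5, 8, 11 and 12, at 0.0405, 0.0407, 0.0342, 0.0479, 0.0358, 0.042 and 0.0328), with Clk, above the floor on 10 arrays, at -0.78 ± 0.15 and per at 0.05 ± 0.11. The glycolysis list had 3 that rose and 4 that fell of 19, with a median of 0.12 and a mean of 0.04 against a downward test (limma camera adjusted p = 0.802). In it Glyp rose by 0.81 ± 0.13 and Hex-A changed by -0.88 ± 0.15. Clock genes that fell numbered 3 without hour 1 or 12, 2 rose without hour 1 or 6, and in glycolysis 2 fell without hour 1, 5 rose without hour 10 and 1 rose without hour 12. The respiratory chain list had 6 that rose and 1 that fell of 68 (limma camera adjusted p = 0.946), but 2 that rose without hour 1, 2, 4 or 12 and 1 without hour 11, 0 that fell without hour 2, 3 or 12 and 2 without hour 4, and the cytosolic ribosomal protein list 1 of 35, RpS5b at 0.49 ± 0.09, or 3 without hour 10 and 2 without hour 6 or 12 (limma camera adjusted p = 0.966, median 0.00, mean 0.03 and a downward test). In the tricarboxylic acid cycle list 3 rose and 1 fell of 14, with a median of -0.02 and a mean of 0.05 (limma camera adjusted p = 0.893), but 0 fell without hour 1 and 2 fell without hour 2 or 11.

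Few probe sets passed for a curved course, in which the middle hours lay above or below a line through the ends. The clock gene tim read 557.3 at hour 1, 178.4 at hour 4 and 378.9 at hour 12, a trough of -1.14 for the middle of the course against its ends (limma adjusted p = 0.0344). Its second probe set did not pass, at -0.34 (limma adjusted p = 0.47). CG4716 had a trough of -1.25 (limma adjusted p = 0.0344), from a fall that flattened, at 613.3 at hour 1, 68.1 at hour 9 and 101.1 at hour 12. Sgp had a peak of 1.40, from 244.2 at hour 1 through 517.1 at hour 5 to 102.9 at hour 12 (limma adjusted p = 0.0424). The remaining call was a peak of a probe set unnamed here. In the gene lists 13 of 34 passed for this term at the preset correlation, such as ribosome biogenesis upward (limma camera adjusted p = 1.81e-13; adjusted p = 0.452 with an estimated correlation) and insulin and TOR signalling downward (limma camera adjusted p = 0.000102; adjusted p = 0.282 with an estimated correlation), and 0 with an estimated one. The 2 peaks and 2 troughs were the only calls of 11586, with 641 probe sets under an unadjusted p of 0.05 against 579 by chance. There were 16 peaks and 8 troughs without hour 10, 2 and 2 without hour 4, 0 and 2 without hour 8, 0 and 1 without hour 11, and 0 of either without hour 1, 2, 3, 5, 6, 7, 9 or 12. With the 3' to 5' difference of any of the 3 control transcripts as covariate there were 0.

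The hours were also compared as 3 windows of 4 hours. From the first to the second window and from the second to the third, Jon25Bii changed by 1.65 and 0.44 and Fad2 by 1.03 and 0.20. No difference in timing was tested. Jon25Bii went from a mean intensity of 540.7 ± 334.3 in hours 1 to 4 to 1512 ± 405.5 in hours 5 to 8 and 2029 ± 418.1 in hours 9 to 12 (SD, n = 4 arrays each). Yp2 went from 638.2 ± 166.1 through 1609 ± 409.6 to 2871 ± 1230. From hours 1 to 4 to hours 9 to 12, limma called 628 probe sets higher and 349 lower, and 947 of these 977 were also called in the linear trend. From hours 1 to 4 to hours 5 to 8 it called 210 higher and 9 lower, the largest rises of named genes above the floor on all 12 arrays being Jon25Bii by 1.65, Yp2 by 1.33, Fad2 by 1.03, CG11267 by 0.90 and CG6295 by 0.87 (limma adjusted p = 0.043, 0.0447, 0.0416, 0.0393 and 0.0434). Lower in that contrast were CG8997 (-0.61), CtsL1 (-0.54), CG34357 (-0.52), Gbeta76C (-0.50) and CG6675 (-0.48). With the floor at the 40th percentile CG8997 had a trend of -0.56 in place of -0.95 and lost its trend call (limma adjusted p = 0.0631), as did CG6675 (0.0587). Other probe sets for CG34357 had trend changes of 0.04 and 0.03, and the called probe set lost its trend call without hour 1 (limma adjusted p = 0.098) or hour 2 (0.0585). Between hours 5 to 8 and hours 9 to 12 limma called 0 probe sets, with 771 under an unadjusted p of 0.05 and a smallest adjusted p of 0.191, but 3 lower without hour 1 and 1 without hour 9. The contrast of hours 5 to 8 with hours 1 to 4 had 0 calls in either direction without hour 1, 2, 6, 7 or 8. It had 1 higher and 0 lower without hour 9, 108 and 38 without hour 4, 410 and 16 without hour 5, 459 and 31 without hour 10, and 84 and 7 without hour 11. Hours 9 to 12 against hours 1 to 4 had 403 higher and 210 lower without hour 1, 268 and 187 without hour 2, 1070 and 417 without hour 10, 246 and 160 without hour 11, 291 and 160 without hour 12, and 0 with the actin 3' to 5' difference as covariate.

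No single hour stood out as a step. The search for a single change point called 0 probe sets, with 2340 under an unadjusted p of 0.05 and a smallest adjusted p of 0.122. There was 1 call higher without hour 6 and 1 lower without hour 8.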

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

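The tests of male transcripts, yeast probe sets, and nerve, eye and muscle markers, and their bounds, were chosen after the values had been seen, as were the random orders for the contrasts with 0 calls. The counts of random orders for the other contrasts were set up before they were seen.

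Readings of control probe sets for yeast genes, outside the fly measurement, fell over the hours. The yeast RIP1 probe set was above the floor on 12 of 12 arrays, at 170.4 at hour 1 and 61.7 at hour 12. URA3 was above it on 11 arrays, WBP1 on 1 and YEL018w on 0. Fitted changes were -0.94 for RIP1, -0.51 for URA3, -1.21 for WBP1 and -0.55 for YEL018w. The mean of RIP1 and URA3, the 2 above the floor on at least 3 arrays, was -0.73 log2. URA3 read 89.5 at hour 1 and 52.4 at hour 12, a level that other control probe sets without a fly target also reached. For RIP1 Pearson r with hour was -0.79 (permutation p = 0.00041, adjusted over 4 probe sets 0.00082; rho = -0.77, permutation p = 0.00505, adjusted 0.00843; r = -0.65 without hours 1 and 12). A drift of dim probe sets is argued against by the 19 other control probe sets without a fly target, spike-in controls aside. Their median change was -0.026 log2. RNA of eaten yeast, most of it soon after the return to yeast, remains a candidate source at -0.73. It cannot be told apart from fly transcripts that bind to these probes, because no array of flies without yeast was analysed here.

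Some transcripts of accessory gland and testis were higher on the arrays of hours 2, 3, 5, 9 and 10 than on the others. Of 16 further gland genes 13, and of 27 testis genes 12, had exactly these as their 5 highest arrays, the latter 44.4% (exact 95% interval 25.5% to 64.7%), against 1.67% of all other probe sets. An offset of most probe sets on exactly these 5 arrays is argued against by the 1.67%. Still, 193 other probe sets had this pattern against 14.6 expected by chance. That share cannot show a difference between arrays that also takes in hour 4. The largest component left after the trend (37.1% of that variance) was positive on these 5 arrays and at hour 4, and negative on the others. Each array was closest, by rank correlation, to an array of the same sign. The signs are spread unevenly over the windows of hours, so the window contrasts cannot be separated from this component. Among the control probe sets, the middle one for 18S rRNA was lowest on these 5 arrays. It read 40.2 to 94.5 there and 97.2 to 337.9 on the others. The 5' and 3' ones for 18S rRNA did not separate the arrays (5' 37.9 at hour 9 and 27.4 at hour 8). Whether the 5 arrays differ in preparation was not tested. RNA of male flies or male tissue in the pools of hours 2, 3, 5, 9 and 10 may be the source of the gland and testis transcripts. However, the other 15 testis genes did not follow. Of these fzo, ProtB, can and djl were under the floor on every array, so their order there says little. The testis gene mia missed the pattern only through hour 4 (93.4, against 86 at hour 2). By contrast, bol and Mst98Ca were above the floor on all 12 arrays without the pattern. The gland transcripts Acp26Aa, Acp53Ea and Acp76A, though higher on the same 5 arrays, stayed under the floor on every array. With the male gland mean as covariate 94.5% of the trend calls were kept. That mean correlated with hour at only -0.18, so this fit could take away little of a slope on hour. It argues only against a linear effect of the male gland mean as the cause of the trend. The mean was low at hour 4, so the fit says nothing of the component that this array shares. On the other 7 arrays Acp95EF was at the floor, while the yolk protein genes Yp1, Yp2 and Yp3 were above it on every array. The sex of the pooled flies stays open, since the labels give none.

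Of 61 nerve, eye and muscle genes 25 fell and 0 rose, with a median change of -0.27, and none of the 3 lists passed with an estimated correlation. An equal dilution of all their markers is argued against by the spread between genes beyond their standard errors, 0.34 log2 (bootstrap 95% interval 0.28 to 0.39), with 11 genes above 0. A smaller share of head and muscle RNA that lowers the markers unequally stays open. The spread cannot decide on it, and the spread of other lists was not compared. RNA quality cannot be told apart from hour: the mean 3' to 5' difference of actin and eIF4A correlates at -0.75 with hour. With it as covariate the median was -0.37, and with all 3 control transcripts averaged it was -0.23, while trend calls over all probe sets numbered 290 and 616, with larger standard errors and changes at a median ratio of 1.02 and 0.90 to those without it. A change of expression within these tissues was not tested.

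Chance order of the arrays can be excluded for the count of trend calls: 1 of 100 orders, the real one, reached 1554, and the highest other count was 0. It can also be excluded for hours 9 to 12 against hours 1 to 4 (1 of 100; real 977, highest other 24). For hours 5 to 8 against hours 1 to 4 the share was 2 of 100 (real 219, highest other 1159). For the mid-course term it was 3 of 100 (real 4, highest other 225). These shares were not adjusted over the contrasts, and other orders gave more calls, so chance order is not taken as excluded. Other orders calling 1159 and 225 point to a structure of the arrays that hour does not describe, and both counts are 0 without hour 1, 2, 6 or 7, so these calls are not taken as an effect of hour. For hours 9 to 12 against hours 5 to 8 and for the step the real count was 0, which 100 of 100 orders reach by necessity (highest others 47 and 3), so the orders say nothing of chance there.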

How the results depend on the processing

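The covariates, the fit without 5 arrays and the list without cyclophilins were chosen after seeing the data; the other settings were chosen before. The trend calls had the same sign in every refit compared except with the floor at the 40th percentile (98.3%), counting the 1232 of 1554 that the strict filter tested. These calls were selected on the same arrays that the refits use, so a shared sign was likely beforehand and does not test them. The number of trend calls moved with the arrays used, with the floor and filter, and with covariates that themselves follow hour. It was 1086 with the floor at the 40th percentile (1020 shared with the 1554) and 1213 with no filter on dim probe sets (1144 shared). Where counts moved, the cause was not tested. Leaving out single hours gave 575 to 1361 higher and 309 to 641 lower in the trend, with 0 to 16 peaks and 0 to 8 troughs. The windows gave 0 to 459 higher and 0 to 38 lower for hours 5 to 8 against 1 to 4, and 0 to 0 higher and 0 to 3 lower for hours 9 to 12 against 5 to 8. Without single hours there were 246 to 1070 higher and 160 to 442 lower for hours 9 to 12 against 1 to 4. They also gave 0 to 1 steps higher and 0 to 1 lower, and 12 to 13 lists higher and 4 to 7 lower. Odd hours gave 441 higher and 233 lower, and even hours 0 and 0. Of the 674 odd-hour calls 665 had the same sign in even hours. Ranks (Spearman) gave 602 higher and 332 lower. Quantile normalization gave 4 peaks, 4 troughs and 61 higher for hours 5 to 8 against 1 to 4. The floor at the 40th percentile gave 1 peak, 1 trough, 0 higher and 0 lower for hours 5 to 8 against 1 to 4, and 398 higher and 175 lower for hours 9 to 12 against 1 to 4. No filter on dim probe sets gave 1 peak, 0 troughs, 0 higher and 0 lower for hours 5 to 8 against 1 to 4, and 190 lower for hours 9 to 12 against 1 to 4; the strict filter gave 1 trough. With the male gland mean as covariate 331 were higher for hours 5 to 8 against 1 to 4, and 2 higher and 6 lower for hours 9 to 12 against 5 to 8. Without the arrays holding male gland transcripts the trend had 525 higher and 323 lower (715 shared). Without them there were 0 peaks, 0 troughs, 344 higher and 17 lower for hours 5 to 8 against 1 to 4, 192 lower for hours 9 to 12 against 1 to 4, and 3 lists lower.

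With the 3' to 5' difference as covariate, trend calls were 62 higher and 166 lower for actin, 431 and 298 for eIF4A, 120 and 170 for actin with eIF4A, and 314 and 302 for all 3 transcripts. Each of these, and GAPDH, gave 0 peaks and 0 troughs, and all but GAPDH gave 0 higher and 0 lower for hours 5 to 8 against 1 to 4, where GAPDH gave 612 and 39. For hours 9 to 12 against 1 to 4 actin, and actin with eIF4A, gave 0 higher and 0 lower, eIF4A 127 and 88, all 3 transcripts 164 and 106, and GAPDH 1041 higher. Lists with the inter-gene correlation estimated per list were 0 higher and 0 lower, while fry called 11 higher and 3 lower. Among the lists fry called were mitochondrial ribosomal proteins (fry adjusted p = 0.000784), the proteasome (0.000769) and the nervous system (0.000638). Ribosome biogenesis (fry adjusted p = 0.0658) and translation factors (0.142) did not pass with it. Outside single left-out hours, list calls were lost 37 times and gained 11 times and named-gene calls lost 389 times and gained 7 times. Signal near the floor limits dim probe sets.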

Other observations

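Enzymes of detoxification changed gene by gene. Of 121 tested genes of this list 16 rose, 6 fell and 99 did not pass (19 rose and 7 fell adjusted over the list alone; limma camera adjusted p = 0.506). The list was drawn by name and took in Cyp1 and Cyp40, which are cyclophilins; without them, a setting chosen after seeing the data, 14 rose and 6 fell of 119 (limma camera adjusted p = 0.692). With the full list 10 rose without hour 2 or 4 and 9 without hour 12, and 3 fell without hour 1 and 1 without hour 11. The glutathione transferase GstE9 rose by 1.19 ± 0.13, and the cytochrome P450 gene Cyp9b2 by 1.26 ± 0.19, though a second probe set of Cyp9b2 had a change of 0.09. Ugt35B1 changed by -0.61 ± 0.10, with a second probe set at 0.08, and Cyp18a1, above the floor on 9 arrays, by -0.72 ± 0.18, a call lost without hour 1 (limma adjusted p = 0.0857) or hour 11 (0.0548). With the floor at the 40th percentile Cyp18a1 changed by -0.16 and lost its call (limma adjusted p = 0.375). The antifungal peptide gene Drs changed by -0.51 ± 0.08 while SPE, a protease of the Toll pathway, rose by 0.52 ± 0.11, in an immune list with 1 that rose and 1 that fell of 15 (limma camera adjusted p = 0.355), or 2 that rose without hour 1 or 8 and 2 that fell without hour 3.

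Cuticle and peritrophic matrix genes included Cpr67B at -0.90 ± 0.15 and Peritrophin-15a at -0.69 ± 0.12, in a list with 2 that rose and 5 that fell of 104 and a median of 0.01 against a downward test (limma camera adjusted p = 0.447). The count that rose was 0 without hour 2, 3 or 11 and 1 without hour 1, 5, 6, 8, 9 or 10. Of 32 odorant-binding and taste genes 3 rose and 2 fell (limma camera adjusted p = 0.506, median 0.02, mean -0.01 and a downward test), but 1 that rose without hour 1, 2, 3, 4, 6, 8 or 9, 0 without hour 11, and 1 that fell without hour 2, 3, 11 or 12. In the autophagy list 2 of 17 fell, Atg8a and Atg1 (limma camera adjusted p = 0.126), and 1 without hour 1, 2, 6, 9, 11 or 12. Likewise in the juvenile hormone and ecdysone list 1 rose and 1 fell of 22 (limma camera adjusted p = 0.403), but 0 of either without hour 1, 0 that fell without hour 11 and 2 that fell without hour 10.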
